A study of Mus musculus with 30 samples.

How the data were processed

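Bone marrow-derived macrophages of C57BL/6N mice were stimulated with TNF, PGE2 or both for 1, 2 or 4 h, or left untreated, with 3 libraries in each of 10 groups. Per the labels' protocols, libraries were made by Smart-seq2, in which polyadenylated RNA is reverse transcribed, the cDNA is amplified by PCR and then fragmented by tagmentation, and no molecular identifiers are used. The authors deposited a table of whole-number counts per gene, not normalized, in which the totals of the libraries differ. STAR 2.5.3a, featureCounts and the mouse build mm10 are named per the submitters' processing notes, with no further detail; the gene annotation and the strand setting are not given in the sources used here. Smart-seq2 does not mark strand, so reads of overlapping antisense genes cannot be told apart. Genes with near-identical copies, such as Ifit3 and Ifit3b, Ifi204 and its neighbours, Oas1a and the class I genes H2-K1 and H2-D1, have uncertain counts where reads could be split or dropped. Because PCR copies of a molecule are counted separately, counting intervals and floors cover counting error only.

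Each table column was matched to a library by its name, and the number of further columns with values per library was 0. Total counts ranged from 15062499 to 35175270, so that 1 count is worth at most 0.0664 CPM in a library. No replicate pair agreed within sampling noise: the chi-square per degree of freedom over genes was between 5.85 and 43.8. The labels number the replicates 1 to 3 but do not say whether they came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. The replicate number was not used in the main model. There is 1 untreated group for all times.

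Counts as deposited were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 13590 of 32245, and libraries were scaled by the trimmed mean of M-values (TMM). A model with a mean per group was fitted to all 30 libraries with robust dispersion and quasi-likelihood estimation, and each contrast was tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. Contrasts were each treatment and time against untreated cells, the combination against each single treatment at the same time, the interaction at each time, and 4 h against 1 h within each treatment. A gene was counted as above (or below) both single treatments when both of the latter contrasts passed the threshold in that direction. CPM are TMM-scaled counts per 1e+06 counts of a library over the genes tested, except the sums of marker genes, which include genes below the filter.

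In all, 20 gene lists and 8 lists of cell type markers were fixed before the data were examined, with the comparisons, the tests and the alternatives. The lists are NF-kB targets, inflammatory cytokines, CXC chemokines attracting neutrophils, CC chemokines, interferon response, cyclic AMP-CREB targets, immediate early genes, regulatory and repair genes, prostaglandin pathway, inflammasome and pyroptosis, pattern recognition receptors, MHC class II, MHC class I, cholesterol synthesis, LXR targets, glycolysis and hypoxia, NRF2 targets, matrix remodelling, cell cycle and macrophage identity, and the marker lists are neutrophil, dendritic cell, T cell, B cell, fibroblast or stromal, erythroid, mast cell or basophil and osteoclast. Each list was tested against the other genes with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 20 lists of a comparison. Of the 420 pairs of a list and a comparison, 236 were called, and 122 of these held with an estimated correlation. All 18 calls of the cyclic AMP-CREB list held, as did 13 of 15 for CXC chemokines, 11 of 18 for NF-kB targets, 10 of 14 for CC chemokines, 3 of 12 for the interferon response and 0 of 4 for MHC class II. Where a list call in the text was lost, the adjusted p with the estimated correlation stands beside it. Counts of list members are over all genes tested, with the count adjusted over the list alone beside them.

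A gene could be named if it belonged to one of the lists, if it was 1 of 8 key genes (Il1b, Tnf, Il6, Il10, Il12b, Ptgs2, Cxcl2 and Cxcl10), or if it was among the 5 largest changes in each direction at a time (10 for 4 h against 1 h) among genes past the threshold with a mean of at least 5 CPM and no overlap between the libraries compared (for the interaction, the same sign when each replicate number was left out in turn). Numbered gene models, mitochondrial and ribosomal protein genes and receptor segments were not named. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and ratios to 1 to 3 counts are given with a 95% exact interval for counting error. Mx1, Mx2, Cxcl11 and Clec7a were not analysed here, and Il12a, Cxcl5, Ccl17, Ereg, Retnla, Slco2a1 and Ptgis had too few counts to be tested. The positions of the key genes are from the GENCODE annotation of GRCm38.

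The main steps were tested on simulated counts drawn from the means of the untreated libraries and the sizes of all libraries. In these, 200 genes were changed in the combination at 4 h only, and no other group had a treatment effect. The real groups differ in far more genes, so the shares recovered and the false calls need not carry over to them. For the combination at 4 h against untreated cells, over 12799 genes, 70.1% of genes changed by 1.5-fold, 74.6% changed by 2-fold and 98.5% changed by 4-fold were recovered, with 3.6% false calls. For the interaction at 4 h the shares were 26.9%, 62.7% and 92.4%, with 4.7% false calls. The alternatives were relative log expression (RLE) size factors of edgeR in place of TMM, and scaling by total count only. Others were no filter on low counts, the Wald test of DESeq2 1.42.0 and a fit of only the groups compared. The last alternatives were the replicate number as a block and leaving out each library in turn. For the lists they were an estimated correlation, the fry test, the replicate block and RLE scaling. A fit without 3 libraries set aside (TNF 4 h replicate 1, TNF+PGE2 4 h replicate 1 and TNF+PGE2 2 h replicate 3) was added after the data were seen. The first 2 of these had the most genes detected, and the third lay farthest from its partners. TNF 4 h replicate 2, which also lay far from its partners (chi-square per degree of freedom 28.9 and 23.2, against 10.0 between the other 2), was kept in that fit and was left out only in the fits that leave out 1 library. Figures were drawn with matplotlib 3.10.9.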

Results

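Macrophages were grown from mouse bone marrow for 7 days in medium conditioned by L929 fibroblasts, a source of the macrophage growth factor M-CSF. They were stimulated with tumour necrosis factor (TNF, 10 ng/mL), an inflammatory cytokine, with prostaglandin E2 (PGE2, 1 µM), a lipid mediator that acts through G protein-coupled receptors, or with both (TNF+PGE2). Cells were collected 1, 2 or 4 h after stimulation, and untreated cells formed a single control group. The series as a whole concerns Il1b-expressing macrophages in pancreatic tumours, and this arm asks how the cytokine and the prostaglandin act on macrophages alone and in combination. There were 10 groups of 3 libraries, 30 libraries in all. Total counts ranged from 15062499 (PGE2 4 h replicate 1) to 35175270 (PGE2 1 h replicate 3). Of 32245 genes in the table, 13590 had enough counts to be tested. Group values below are mean CPM (scaled counts per 1e+06) ± SD of 3 libraries, and changes are log2 fold changes ± SE from the edgeR fit of 30 libraries. The words rose and fell are used only of genes with an adjusted p under 0.05.

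**Figure D1:**
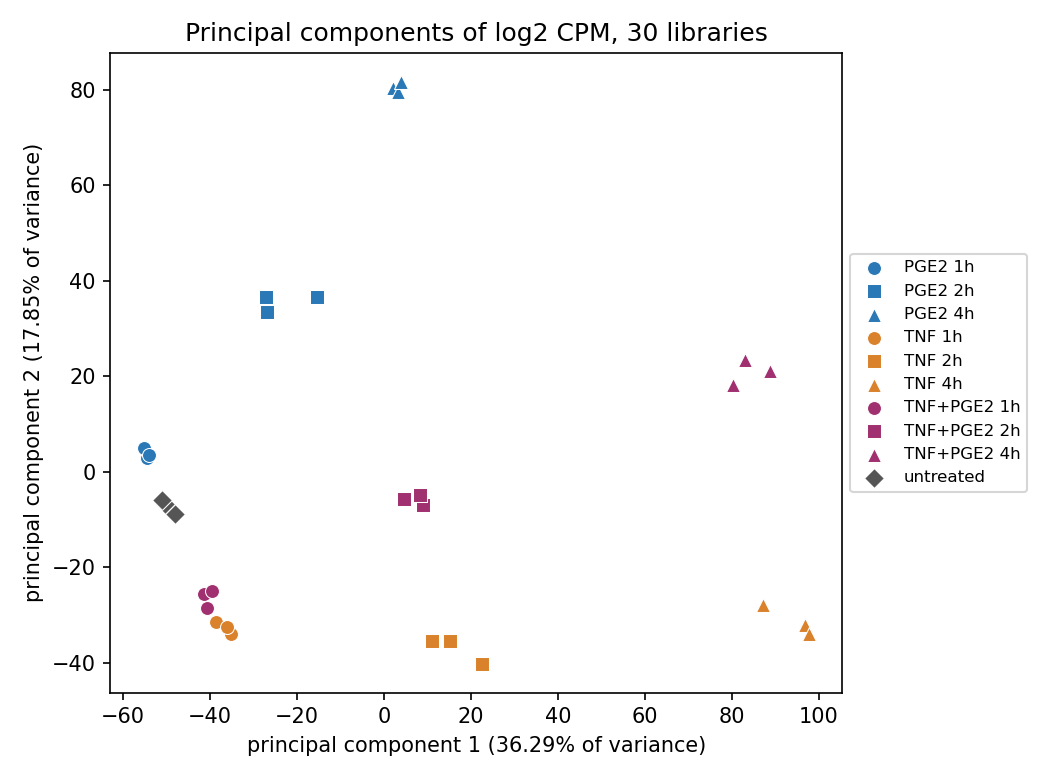
Each of the 30 libraries is placed by the first principal components of log2 CPM, with component 1 (36.29% of variance) on the x axis and component 2 (17.85%) on the y axis; colour gives the treatment and marker shape the time. The libraries of a group lie near each other, TNF and the combination at 4 h lie farthest right, and PGE2 at 4 h lies highest.

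Key genes were fixed in advance. On the GRCm38 assembly, the annotation places Il1b, the gene of interleukin-1β, on chromosome 2 from 129364570 to 129371139, Tnf on chromosome 17 from 35199381 to 35202007 and Il6 on chromosome 5 from 30013114 to 30019981. Il10, which encodes an anti-inflammatory cytokine, lies on chromosome 1 from 131019845 to 131024974, and Ptgs2, which encodes the inducible cyclooxygenase of prostaglandin synthesis, lies on the same chromosome from 150100031 to 150108227. Il12b, a subunit of interleukin-12, lies on chromosome 11 from 44400063 to 44414033. The chemokine genes Cxcl2 (90903871 to 90905938) and Cxcl10 (92346638 to 92348889) lie on chromosome 5. All 8 are protein-coding genes, and their counts are totals per gene rather than per exon.

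PGE2 alone was compared with untreated cells to find what the prostaglandin does without TNF. After 1 h the leading increases included Areg, the growth factor amphiregulin (6.65 ± 0.34), Ptgs2 (5.44 ± 0.13), Ramp3, a modulator of peptide hormone receptors (5.23 ± 0.47), and Gprc5a, an orphan receptor (3.88 ± 0.20). Without untreated replicate 1 the values of Areg and Ramp3 were 10.06 and 8.65. Ramp3 stood at 8.35 ± 0.36 at 4 h and Ptgs2 at 1.85 ± 0.13. Il1b rose from 63.5 ± 1.30 CPM in untreated cells to 225 ± 32.8 CPM at 1 h and was down to 13.0 ± 0.338 CPM at 4 h (-2.29 ± 0.19, adjusted p = 5.51e-10). Tnf fell at every time (-0.43 ± 0.08, -0.71 ± 0.08 and -1.60 ± 0.09). Neutrophil-attracting CXC chemokines were called as higher at 1 h, with 2 of 4 members higher and 1 lower (3 and 1 adjusted over the list alone). At 2 h they were called with 2 higher and 0 lower (2 and 0, adjusted p = 0.051 with an estimated correlation). At 4 h they were not called (adjusted p = 0.296). Among the CC chemokines, Ccl3 and Ccl4, which attract monocytes and T cells, fell at 2 h (-3.64 ± 0.13 and -2.43 ± 0.10) and 4 h (-3.49 ± 0.13 and -4.02 ± 0.12). The CC list was called as lower at 1 h, with 0 of 10 members higher and 5 lower (1 and 5 adjusted over the list alone). At 2 h it was not called, with 4 higher and 4 lower (4 and 4, adjusted p = 0.381). At 4 h it was called as lower, with 3 higher and 4 lower (3 and 4, adjusted p = 0.11 with an estimated correlation).

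Genes known to be driven by cyclic AMP and the transcription factor CREB rose with PGE2 as a group at 1 h, with 15 of 18 members higher (16 adjusted over the list alone) and a median of 1.59. Nr4a2, an orphan nuclear receptor (3.49 ± 0.12), Crem, a cyclic AMP-responsive transcription factor (3.04 ± 0.09), Sik1, a kinase that restrains CREB coactivators (2.24 ± 0.13), and the phosphodiesterase gene Pde4b (2.49 ± 0.07) were among them. By 4 h the list had split, with 8 of 18 members higher and 7 lower (8 and 7 adjusted over the list alone). Its median was 0.50 and its mean -0.08, with no call (adjusted p = 0.985). Crem was still up (3.25 ± 0.09), but Fosb was at -5.54 ± 0.20 and Nr4a1 at -4.41 ± 0.17. Immediate early genes, transcription factors switched on within minutes of a stimulus, were called as higher at 1 h, with 7 of 16 members higher and 6 lower (8 and 7 adjusted over the list alone) and a mean of 0.45, and were mostly below untreated cells at 4 h, with 1 of 16 members higher and 14 lower (1 and 14 adjusted over the list alone). Egr2, Atf3 and Egr1 changed by -7.11 ± 0.20, -6.59 ± 0.14 and -6.46 ± 0.19. NF-kB targets were called as higher at 1 h, with 9 of 21 members higher and 3 lower (11 and 5 adjusted over the list alone, adjusted p = 0.058 with an estimated correlation). They were called as lower at 4 h, with 1 of 21 members higher and 15 lower (1 and 15 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation). Relb, a subunit of NF-kB, was then at -2.32 ± 0.13 and Icam1, an adhesion molecule, at -1.60 ± 0.11.

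Most cholesterol synthesis genes rose with PGE2 at 4 h, with 17 of 19 members higher and 1 lower (18 and 1 adjusted over the list alone) and a list median of 1.27. They were led by Fdft1 (2.43 ± 0.11) and Sqle (2.19 ± 0.10), enzymes of squalene formation and oxidation. In the regulatory and repair list, Arg1, the arginine-degrading enzyme arginase, rose to 4.75 ± 0.34 at 4 h and Thbs1, the matrix protein thrombospondin, from 3728 ± 235 CPM to 22410 ± 1450 CPM. The list as a whole was not called at 4 h, with 5 of 16 members higher and 7 lower (6 and 7 adjusted over the list alone, adjusted p = 0.974). It was called at 2 h, with 9 of 16 members higher and 2 lower (9 and 2 adjusted over the list alone, adjusted p = 0.051 with an estimated correlation). MHC class I genes were lower at 4 h, with 11 of 11 members lower (11 adjusted over the list alone) and a median of -0.39 (adjusted p = 0.36 with an estimated correlation). Inflammasome genes were also lower at 4 h, with 2 of 12 members higher and 10 lower (2 and 10 adjusted over the list alone, adjusted p = 0.065 with an estimated correlation). Casp4, a caspase that senses lipopolysaccharide, was at -2.38 ± 0.13 and the sensor gene Nlrp3 at -1.63 ± 0.09. Macrophage identity genes fell in part at 4 h, with 1 of 18 members higher and 11 lower (1 and 12 adjusted over the list alone, adjusted p = 0.074 with an estimated correlation). Cx3cr1, the fractalkine receptor, was at -3.38 ± 0.25 and Gpr34 at -3.79 ± 0.22. The summed neutrophil markers were also lower, at 215 ± 15.0 CPM in untreated cells and 103 ± 9.02 CPM with PGE2 at 4 h. Cell cycle genes were lower at 2 h, with 1 of 25 members higher and 19 lower (1 and 20 adjusted over the list alone, adjusted p = 0.13 with an estimated correlation). This was shared by the treatments: the list median at 2 h was -0.705 with PGE2, -0.622 with TNF and -0.813 with the combination.

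In all, 751 genes rose and 509 fell at 1 h, 2603 and 2354 at 2 h, and 3438 and 3573 at 4 h. The share of higher calls was 59.6% at 1 h and 52.5% at 2 h, against 48.6% and 27.8% with scaling by total count only, which moved the median gene by -0.199 at 2 h. A single untreated group served all times, so changes at 2 h and 4 h include any change over time in culture.

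TNF alone was compared with untreated cells to find what the cytokine does without the prostaglandin. All 21 NF-kB targets rose at 1 h (21 adjusted over the list alone), with a median of 2.14. The inhibitor gene Nfkbia was at 2.96 ± 0.09, Tnfaip3, a brake on the pathway, at 3.02 ± 0.08 and Traf1 at 3.22 ± 0.19. Of the list, 20 were higher at 2 h (20 adjusted over the list alone), and at 4 h 19 were higher and 1 lower (19 and 1 adjusted over the list alone). Tnf itself rose from 51.6 ± 3.87 CPM to 340.4 ± 33.6 CPM at 1 h and 751 ± 50.7 CPM at 4 h. Il1b was 884 ± 35.1 CPM at 1 h and 245 ± 68.9 CPM at 4 h. Il6 and Il12b had 0 counts in the 3 untreated libraries: against the floor of 3 counts over the group, Il6 was at least 125-fold higher and Il12b at least 298-fold higher at 4 h. The inflammatory cytokine list as a whole was higher at 1 h, with 10 of 17 members higher (12 adjusted over the list alone).

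Interferon response genes rose late. The list was not called at 1 h (adjusted p = 0.68), with 3 of 24 members higher (3 adjusted over the list alone). At 2 h it was, with 24 of 24 members higher (24 adjusted over the list alone) and a median of 2.18 (adjusted p = 0.2 with an estimated correlation). At 4 h it was called with 24 of 24 members higher (24 adjusted over the list alone) and a median of 6.80. Cxcl10, a chemokine that attracts T cells, went from 2.02 ± 1.15 CPM to 6848 ± 1470 CPM, and the antiviral genes Ifit1 and Ifit2 changed by 10.41 ± 0.57 and 8.63 ± 0.52. Ifnb1, the gene of interferon-β, had 2 counts in untreated cells and 209 at 4 h, a ratio of 128 with a 95% counting interval from 35 to 1070. CC chemokines rose at 4 h, with 10 of 10 members higher (10 adjusted over the list alone) and a median of 2.75, including Ccl5 (8.35 ± 0.43) and Ccl12 (6.15 ± 0.19). Among neutrophil-attracting CXC chemokines, Cxcl1 (5.29 ± 0.28), Cxcl2 (4.98 ± 0.17) and Cxcl3 (4.35 ± 0.64) rose by 1 h, whereas Ppbp fell (-2.09 ± 0.34).

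MHC class I genes rose at 4 h, with 11 of 11 members higher (11 adjusted over the list alone) and a median of 1.85. The transactivator gene Nlrc5 was at 4.19 ± 0.20 and the peptide transporter gene Tap1 at 3.23 ± 0.14. The MHC class II list was not called, with 6 of 11 members higher and 1 lower (6 and 2 adjusted over the list alone, adjusted p = 0.332). Most pattern recognition receptors rose, with 13 of 19 members higher and 3 lower (13 and 3 adjusted over the list alone), led by the lectin gene Clec4e (5.47 ± 0.12) and Tlr3 (3.59 ± 0.18). Most inflammasome genes rose too, with 9 of 12 members higher and 2 lower (9 and 2 adjusted over the list alone). Most matrix remodelling genes rose, with 10 of 12 members higher (10 adjusted over the list alone, adjusted p = 0.053 with an estimated correlation). The collagenase gene Mmp13 was at 4.03 ± 0.24 and Mmp14 at 5.46 ± 0.29. Most cholesterol synthesis genes rose, with 17 of 19 members higher and 1 lower (17 and 1 adjusted over the list alone). The NRF2 list was called as well, with 7 of 11 members higher and 2 lower (7 and 2 adjusted over the list alone, adjusted p = 0.053 with an estimated correlation). Its member Slc7a11, a cystine transporter gene, was at 4.10 ± 0.17. The cyclic AMP-CREB list was called as higher at 1 h, with 6 of 18 members higher and 5 lower (6 and 5 adjusted over the list alone) and a mean of 0.68. It was called as lower at 2 h, with 5 of 18 members higher and 9 lower (5 and 10 adjusted over the list alone), and at 4 h, with 6 of 18 members higher and 10 lower (6 and 10 adjusted over the list alone), when Nr4a1 dropped from 426 ± 9.29 CPM to 1.36 ± 0.916 CPM. Other leading changes were Acod1, which makes itaconate (10.61 ± 0.41), Ch25h, which makes 25-hydroxycholesterol (10.09 ± 0.35), and Olr1, a scavenger receptor (8.79 ± 0.26 at 2 h).

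With TNF, 754 genes rose and 379 fell at 1 h, 2906 and 2593 at 2 h, and 4092 and 4204 at 4 h. In all 3 treatments alike, 1291 genes were higher and 1335 lower than in untreated cells at 2 h, and 1764 and 2119 at 4 h. As for PGE2, changes at 2 h and 4 h include any change over time in culture. The number lower at 1 h was 232 without TNF 1 h replicate 2, 240 without TNF 1 h replicate 3 and 250 without untreated replicate 1. The share of higher calls was 66.5%, 52.8% and 49.3% at 1, 2 and 4 h. It was 56.5%, 29.2% and 29.7% with scaling by total count only, which moved the median gene by -0.202 at 2 h and -0.330 at 4 h.

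**Figure D2:**
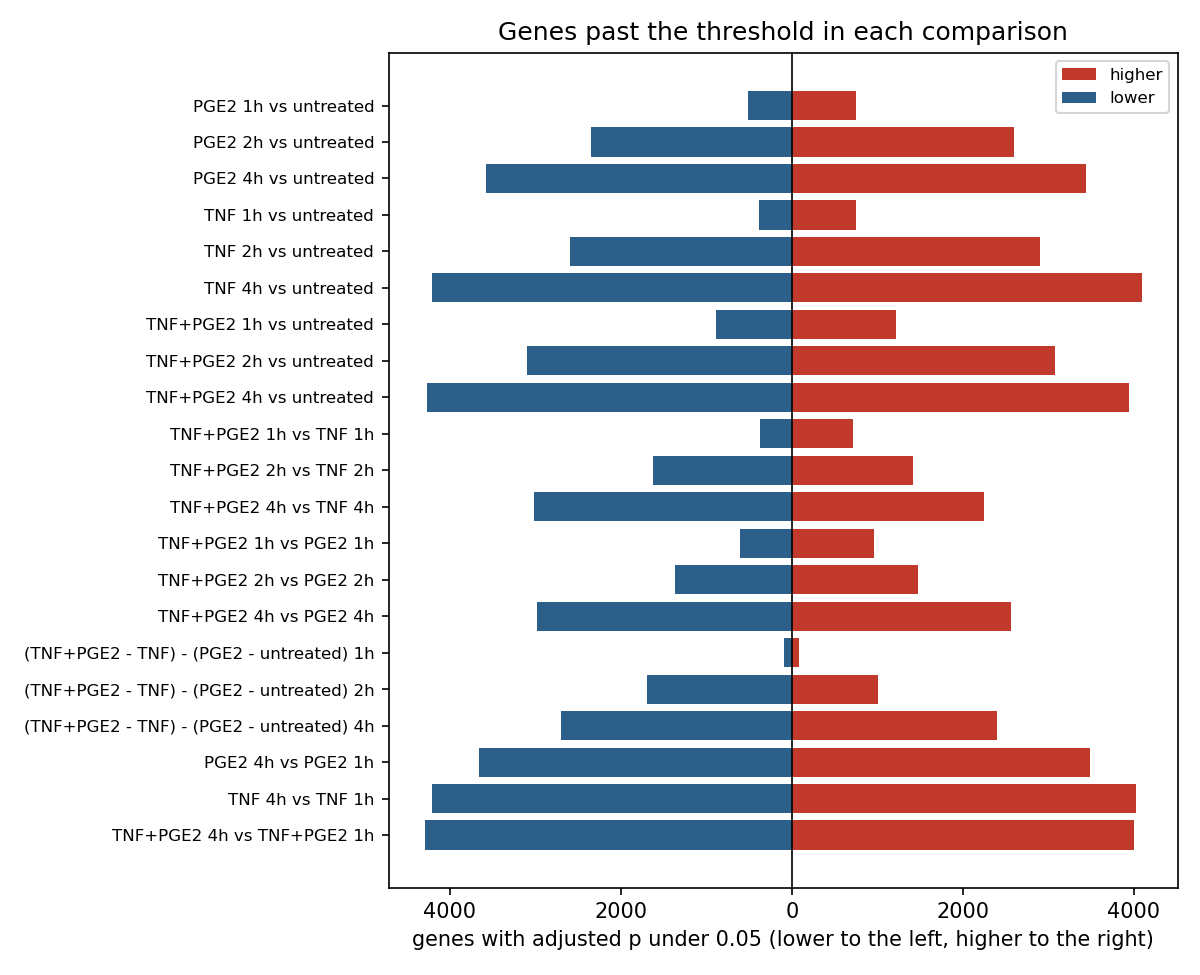
Bars give the number of genes with an adjusted p under 0.05 in each comparison, higher to the right of 0 and lower to the left. The numbers grow with time, from 751 higher with PGE2 and 754 with TNF at 1 h to 3438 and 4092 at 4 h.

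TNF and PGE2 together were compared with untreated cells to describe the state the combination gives. Il1b rose from 63.5 ± 1.30 CPM to 2712 ± 193 CPM at 1 h, 3329 ± 481 CPM at 2 h and 2973 ± 301 CPM at 4 h. Il10 reached 132 ± 6.70 CPM at 2 h and Ptgs2 423 ± 26.6 CPM at 1 h, from 1.94 ± 0.299 CPM and 4.15 ± 1.06 CPM. Neutrophil-attracting chemokines were high at 4 h, with Cxcl3 at 10.82 ± 0.38 and Cxcl1 at 6.77 ± 0.28. All 24 interferon response genes rose at 4 h (24 adjusted over the list alone), with a median of 5.14 (adjusted p = 0.052 with an estimated correlation). Of 21 NF-kB targets 20 rose (20 adjusted over the list alone), with a list median of 2.59.

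The NRF2 list, genes of the oxidative stress response, reached a median of 1.95 at 4 h, with 8 of 11 members higher and 1 lower (8 and 1 adjusted over the list alone). MHC class II genes were higher at 2 h, with 7 of 11 members higher (7 adjusted over the list alone, adjusted p = 0.3 with an estimated correlation). The summed dendritic cell markers stood at 14.0 ± 0.508 CPM in untreated cells and 43.2 ± 4.38 CPM with the combination at 2 h. LXR targets, which include genes of cholesterol export, were mixed at 2 h, with 6 of 10 members higher and 3 lower (6 and 3 adjusted over the list alone), with no call for the list (adjusted p = 0.58). The glycolysis and hypoxia list was called at 4 h, with 8 of 19 members higher and 4 lower (8 and 4 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation), with a median of 0.06 that scaling by total count only turned to -0.18. Its members Hk2, a hexokinase, and Slc16a3, a lactate exporter, rose (3.42 ± 0.13 and 2.98 ± 0.09). Ramp3 (9.70 ± 0.35) and Acod1 (9.20 ± 0.40) were among the largest increases, and Egr3 (-7.99 ± 0.35), Fosb (-7.97 ± 0.25), Egr1 (-6.78 ± 0.20) and Atf3 (-6.11 ± 0.13) among the largest decreases.

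With the combination, 1216 genes rose and 883 fell at 1 h, 3083 and 3099 at 2 h and 3947 and 4265 at 4 h. At 2 h and 4 h these counts, too, include any change over time in culture. The share of higher calls was 57.9%, 49.9% and 48.1% at 1, 2 and 4 h. It was 33.2%, 22.7% and 33.3% with scaling by total count only, which moved the median gene by -0.135, -0.308 and -0.241.

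**Figure D3:**
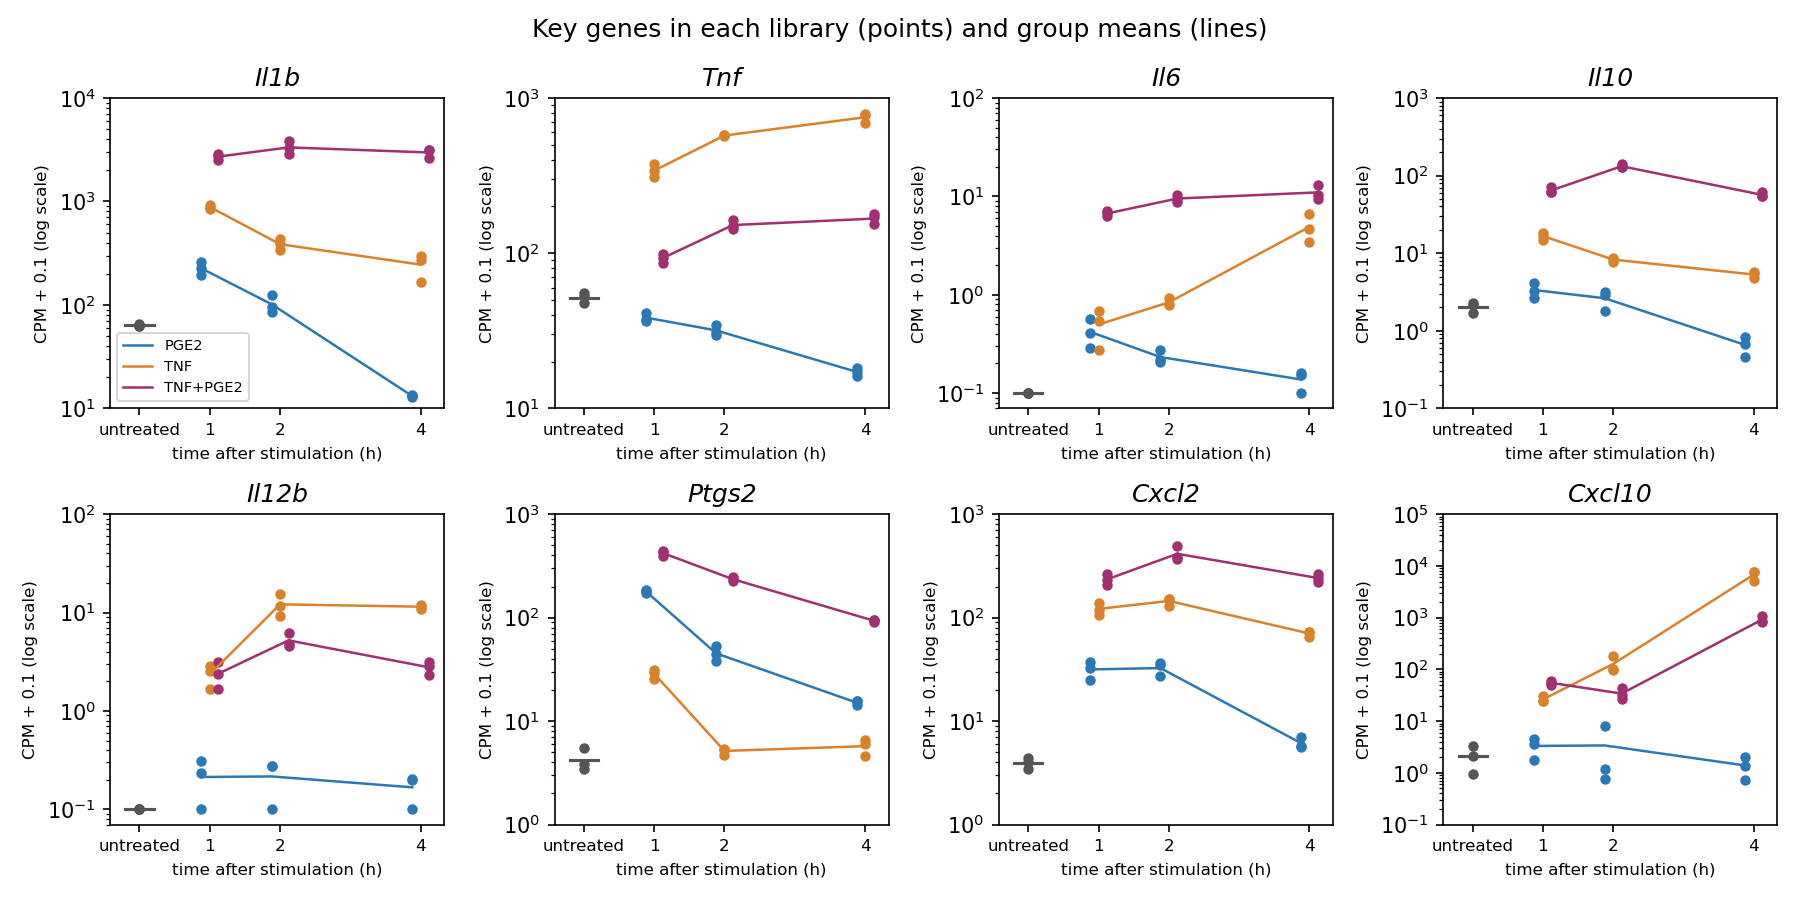
For each of the 8 key genes, CPM + 0.1 is plotted on a log scale against the time after stimulation in h, with untreated libraries on the left; points are libraries and lines are group means. At 4 h Il1b libraries with the combination lie above those with TNF alone, and Tnf libraries lie below them.

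Adding PGE2 to TNF was tested by comparing the combination with TNF alone at each time. Il1b was higher with the combination at 1 h (1.62 ± 0.16), 2 h (3.11 ± 0.17) and 4 h (3.60 ± 0.18, adjusted p = 8.37e-14). At 4 h each of the 3 libraries lay above every library with TNF alone, 245 ± 68.9 CPM with TNF against 2973 ± 301 CPM with both. Tnf went the other way (-1.87 ± 0.08, -1.92 ± 0.08 and -2.17 ± 0.08). Il10 (3.44 ± 0.14), Ptgs2 (4.06 ± 0.13), Il6 (1.18 ± 0.25) and Cxcl2 (1.78 ± 0.13) were higher at 4 h, and Il12b (-2.09 ± 0.30) and Cxcl10 (-2.89 ± 0.39) were lower. Il6 was already 4.04 ± 0.31 higher at 1 h.

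The chemokine families parted. Each of the 4 neutrophil-attracting CXC chemokines was higher with the combination at 4 h (4 adjusted over the list alone), with Cxcl3 at 4.12 ± 0.22 and Cxcl1 at 3.41 ± 0.21. CC chemokines were lower, with 9 of 10 members lower (9 adjusted over the list alone) and a median of -1.15. They were led by Ccl3 (-4.95 ± 0.13), Ccl12 (-4.13 ± 0.17) and Ccl4 (-3.93 ± 0.11), a difference already seen at 1 h for Ccl3 (-1.72 ± 0.11). Interferon response genes were lower at 4 h, with 23 of 24 members lower (24 adjusted over the list alone) and a median of -1.49 (adjusted p = 0.29 with an estimated correlation). Ifit2 was at -2.99 ± 0.40 and Cxcl9, a T cell-attracting chemokine, at -3.62 ± 0.43. MHC class I genes were also lower, with 9 of 11 members lower (9 adjusted over the list alone) and a median of -0.78 (adjusted p = 0.14 with an estimated correlation). Pattern recognition receptors were mostly lower, with 5 of 19 members higher and 12 lower (5 and 12 adjusted over the list alone, adjusted p = 0.29 with an estimated correlation). Without the 3 libraries set aside, 20 of 24 interferon response genes and 9 of 10 CC chemokines were lower.

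The cyclic AMP-CREB list was higher at every time, with 15, 16 and 13 of 18 past the threshold and 0, 0 and 1 lower (15, 16 and 15 higher and 0, 0 and 1 lower adjusted over the list alone) and medians of 1.28, 2.22 and 1.91. Areg (8.91 ± 0.27 at 2 h), Nr4a2 (5.66 ± 0.16 at 2 h), Crem (3.72 ± 0.10) and Fosl2 (3.90 ± 0.10) were members. Regulatory and repair genes were higher at 4 h, with 11 of 16 members higher and 3 lower (11 and 3 adjusted over the list alone). Among them were Thbs1 (5.17 ± 0.09), Arg1 (2.87 ± 0.28), the angiogenic factor gene Vegfa (1.80 ± 0.13) and Il4ra (1.31 ± 0.09). The cytokine gene Osm was 2.40 ± 0.11 higher. In the prostaglandin pathway, Ptgs2 and the PGE2 synthase gene Ptges (2.62 ± 0.21) were higher and the receptor gene Ptger4 was lower (-1.84 ± 0.16). The list went both ways, with 4 of 15 members higher and 5 lower (5 and 5 adjusted over the list alone), a median of -0.20, a mean of 0.01 and no call for the list (adjusted p = 0.163). Macrophage identity genes were lower at 4 h, with 1 of 18 members higher and 12 lower (1 and 12 adjusted over the list alone). Cx3cr1 was at -3.94 ± 0.22 and the transcription factor genes Cebpa and Irf8 at -2.32 ± 0.27 and -2.38 ± 0.09. The summed dendritic cell markers stood at 27.1 ± 3.91 CPM with TNF and 42.0 ± 3.69 CPM with the combination. Such a sum does not show how many members moved. Ddit4, an inhibitor of mTOR signalling, was among the largest increases (6.38 ± 0.40).

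Relative to TNF alone, 712 genes were higher and 369 lower at 1 h, 1420 and 1627 at 2 h and 2244 and 3012 at 4 h. The number lower at 1 h was 229 without TNF+PGE2 1 h replicate 1, and with only the groups compared in the fit it was 1013 at 2 h. The share of higher calls was 65.9%, 46.6% and 42.7% at 1, 2 and 4 h. It was 40.5%, 29.5% and 54.3% with scaling by total count only, which moved the median gene by -0.107 at 2 h.

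Adding TNF to PGE2 was tested by comparing the combination with PGE2 alone. NF-kB targets were higher at every time, 20, 21 and 21 of 21 (20, 21 and 21 adjusted over the list alone), with a median of 3.71 at 4 h. Il1b was 3.59 ± 0.18 higher at 1 h and 7.83 ± 0.22 at 4 h, and Tnf 1.27 ± 0.08 and 3.29 ± 0.09. Il10 (6.62 ± 0.20), Ptgs2 (2.64 ± 0.11), Cxcl2 (5.33 ± 0.17) and Cxcl10 (9.51 ± 0.61) were higher at 4 h, as were Acod1 (10.88 ± 0.45) and the costimulatory receptor gene Cd40 (8.05 ± 0.38). Il12b, at 4 counts with PGE2 alone, was 5.14 ± 0.57 higher at 4 h, and Il6, at 2 counts, was 310 times as high with a 95% counting interval from 85.5 to 2570.

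Interferon response genes were higher at 4 h, with 24 of 24 members higher (24 adjusted over the list alone) and a median of 4.55. MHC class I genes were higher, with 11 of 11 members higher (11 adjusted over the list alone), and so were immediate early genes, with 12 of 16 members higher (12 adjusted over the list alone). The cyclic AMP-CREB list was called as higher at 1 h, with 4 of 18 members higher and 5 lower (7 and 7 adjusted over the list alone) and a mean of 0.41, and at 2 h, with 6 of 18 members higher and 6 lower (6 and 7 adjusted over the list alone), a mean of 0.31 and a median of -0.15. It was mixed at 4 h, with 5 of 18 members higher and 10 lower (5 and 10 adjusted over the list alone). At 4 h its median was -0.65 and its mean 0.06, with no call (adjusted p = 0.789). Gem, a small GTPase, was at 7.14 ± 0.29 and Fosb at -2.43 ± 0.28. Cnr2, the peripheral cannabinoid receptor (-3.54 ± 0.21), Cebpa (-3.26 ± 0.26) and Gpr183, an oxysterol receptor (-3.10 ± 0.21), were among the largest decreases.

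Relative to PGE2 alone, 964 genes were higher and 609 lower at 1 h, 1471 and 1363 at 2 h and 2568 and 2976 at 4 h. With only the groups compared in the fit the number lower at 2 h was 740. The share of higher calls was 61.3%, 51.9% and 46.3% at 1, 2 and 4 h. It was 41.1%, 32.5% and 23.8% with scaling by total count only, which moved the median gene by -0.110 at 2 h and -0.245 at 4 h.

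**Figure D4:**
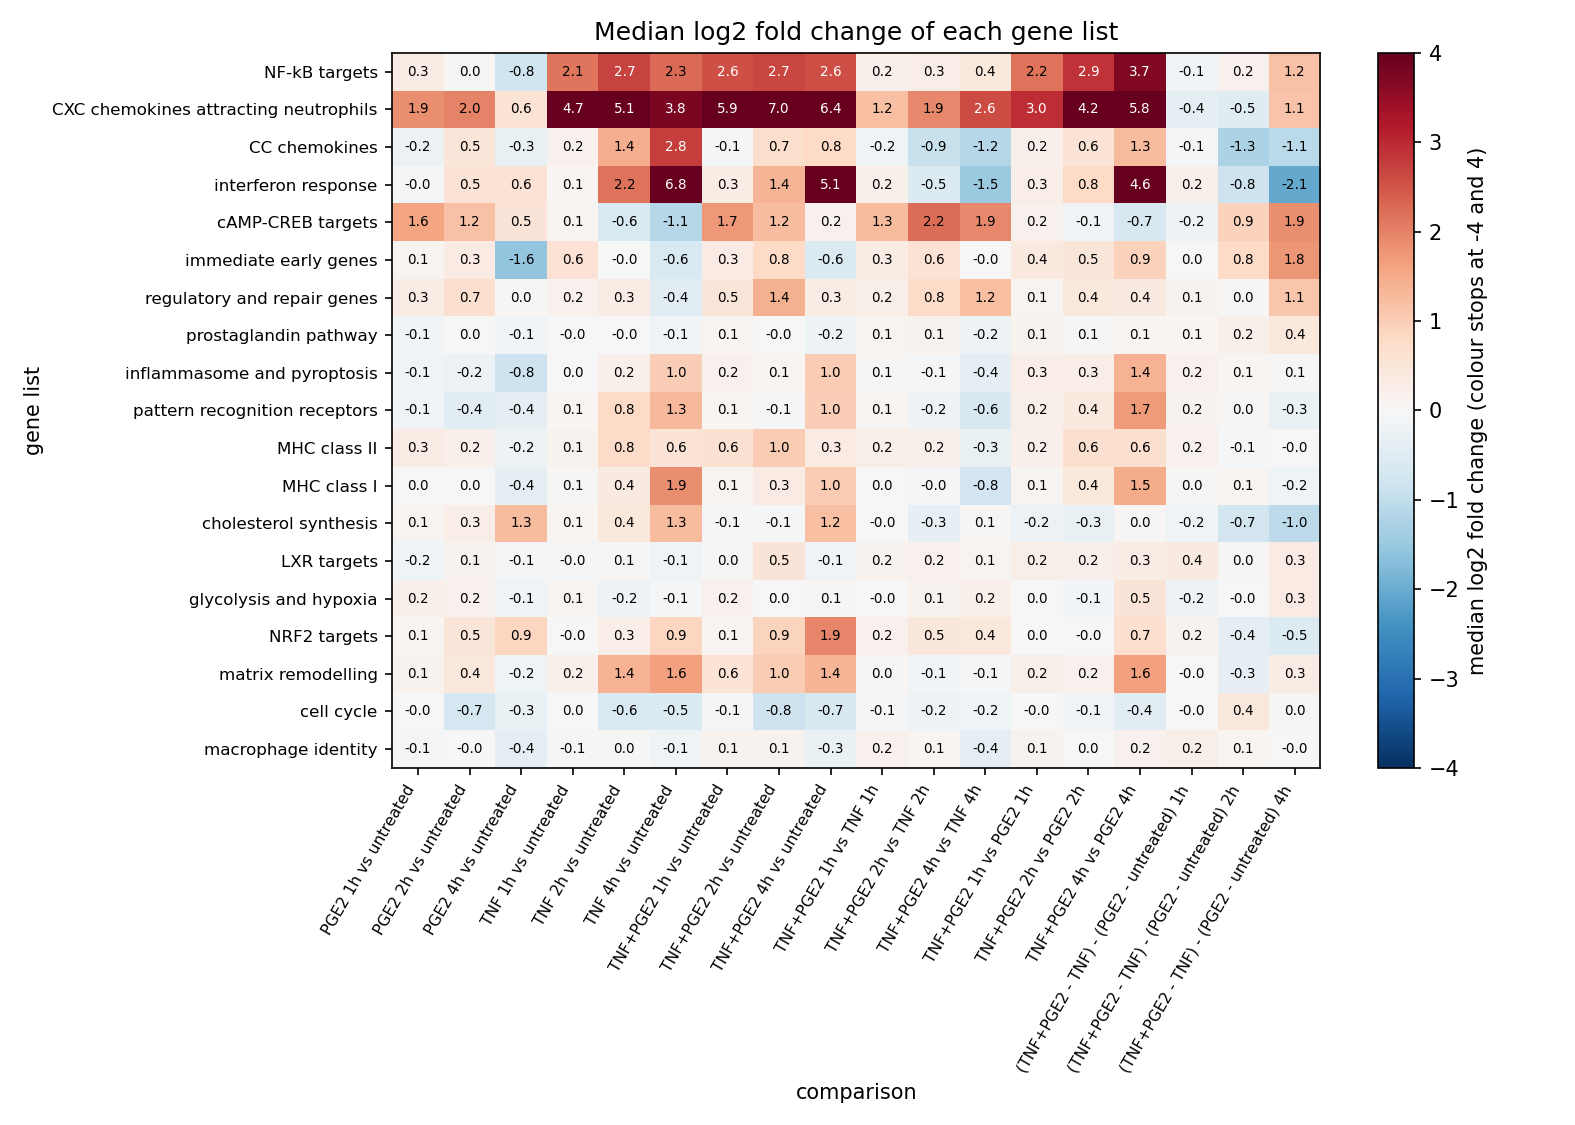
The colour and the number in each cell give the median log2 fold change of a gene list (y axis) in a comparison (x axis), with colours that stop at -4 and 4; the inflammatory cytokine list, with members at 0 counts, is left out. Among comparisons with untreated cells, the interferon response list has its highest medians at 4 h with TNF (6.80) and the combination (5.14), and medians near 0 can change sign with scaling by total count only, as for glycolysis and hypoxia with the combination at 4 h.

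Whether the effects of TNF and PGE2 add up on the log2 scale was tested with the interaction, the PGE2 effect in the presence of TNF minus its effect in untreated cells. At 4 h Il1b stood 5.89 ± 0.26 above the sum: PGE2 alone changed it by -2.29 ± 0.19 and PGE2 added to TNF by 3.60 ± 0.18. Il10 (5.21 ± 0.29) and Socs3, a feedback inhibitor of cytokine signalling (3.59 ± 0.23), fell with PGE2 alone (-1.77 ± 0.27 and -2.46 ± 0.17) and were higher when it was added to TNF (3.44 ± 0.14 and 1.13 ± 0.15). Ptgs2 (2.21 ± 0.19) and Cxcl2 (1.14 ± 0.24) were also above the sum. Tnf was below it (-0.57 ± 0.12), and Cxcl10 did not pass the test (-2.20 ± 1.00), though it did with DESeq2 at -2.24 and with only the groups compared in the fit at -2.10. At 1 h Il10 was above the sum (1.22 ± 0.22) and Cxcl2 (-2.08 ± 0.21), Ptgs2 (-1.56 ± 0.16) and Tnf (-1.45 ± 0.11) were below it, while Il1b was at -0.21 ± 0.23.

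Among gene lists at 4 h, immediate early genes were above the sum, with 15 of 16 members past the threshold above it (15 adjusted over the list alone) and a median of 1.78. Egr2 was at 4.34 ± 0.28 and Klf4 at 4.01 ± 0.25. Between the combination and TNF alone the list median was -0.026, with 6 of 16 members higher and 4 lower. Between PGE2 and untreated cells it was -1.569. A fall over time in culture shared by all treated cells would also put these genes above the sum. Cyclic AMP-CREB targets were above it too, with 12 of 18 members past the threshold above it and 3 below it (12 and 3 adjusted over the list alone), whereas at 1 h they were called as below it, with 2 of 18 members past the threshold below it (6 adjusted over the list alone). At 4 h Nr4a1 was at 8.10 ± 0.28 and Fosb at 7.91 ± 0.55. Both had fallen with PGE2 alone against untreated cells, so a shared fall over time would enter these values. Against untreated cells Fosb stood at -10.34 ± 0.30 with TNF and -7.97 ± 0.25 with the combination. NF-kB targets were above the sum, with a median of 1.18. Of 21 members, 18 were past the threshold above it and 2 below it (18 and 2 adjusted over the list alone). Between the combination and TNF alone their median was 0.421, with 13 members higher and 6 lower. Between PGE2 and untreated cells it was -0.810, with 1 higher and 15 lower, and a shared fall over time would enter there. Cholesterol synthesis genes were below the sum, with a median of -1.03. Of 19 members, 16 were past the threshold below it (17 adjusted over the list alone). Sqle, for example, was 2.19 ± 0.10 with PGE2, 1.49 ± 0.09 with TNF and 2.01 ± 0.10 with both. Against untreated cells the list median was 1.275 with PGE2, 1.252 with TNF and 1.197 with both. The combination differed from TNF by a median of 0.062 and from PGE2 by 0.048. A rise over time in culture shared by all treated cells would also put this list below the sum, and untreated cells of that time were lacking. Interferon response genes were below the sum, with 1 of 24 members past the threshold above it and 18 below it (1 and 19 adjusted over the list alone) and a median of -2.06 (adjusted p = 0.36 with an estimated correlation). CC chemokines were below it as well, with 0 of 10 members past the threshold above it and 7 below it (1 and 7 adjusted over the list alone). Kdr, a receptor for vascular endothelial growth factor, was among the lowest (-5.06 ± 0.26).

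The interaction passed the threshold in 169 genes at 1 h, 82 above and 87 below the sum, in 2708 at 2 h, 1009 above and 1699 below, and in 5106 at 4 h, 2405 above and 2701 below. Of these genes, 47, 1457 and 2675 had moved the same way in all 3 treatments, and a change over time in culture shared by all treated cells would also enter the interaction. The count at 1 h was unstable, 321 with only the groups compared in the fit, 302 with DESeq2, 301 without the filter on low counts and 258 without the 3 libraries set aside. It was 100 without untreated replicate 1, 101, 110, 109, 110 and 111 without TNF replicate 3, TNF replicate 2, TNF+PGE2 replicate 1, PGE2 replicate 3 and untreated replicate 2. The share above the sum was 48.5%, 37.3% and 47.1% at 1, 2 and 4 h against 33.7%, 53.3% and 55.8% with scaling by total count only.

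Genes past the threshold in the same direction against both single treatments were counted at each time. With the combination, 258 genes were above both at 1 h, 398 at 2 h and 660 at 4 h, and 82, 364 and 841 were below both. Il1b, Il10, Ptgs2, Il6 and Cxcl2 were above both at each of the 3 times. Of the genes above both, 28, 111 and 358 also had an interaction above 0 past the threshold, and 17, 73 and 78 had one below 0. The count below both at 1 h was 47 without TNF+PGE2 1 h replicate 1 and 126 without the 3 libraries set aside, and at 2 h it was 193 with only the groups compared and 229 without TNF 2 h replicate 2. With scaling by total count only it was 254 at 1 h and 862 at 2 h.

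Time was examined within each treatment by comparing 4 h with 1 h. Under TNF the interferon genes Ifit1 (10.67 ± 0.57), Cmpk2 (9.54 ± 0.49) and Usp18 (8.70 ± 0.38) were among those that rose most. Fosb (-10.68 ± 0.30), Nr4a1 (-8.96 ± 0.23) and the clock gene Nr1d1 (-4.98 ± 0.26) were among those that fell most. Under PGE2 the largest rises included Fam20a, a secretory pathway pseudokinase (9.10 ± 0.47), Ptprf (6.16 ± 0.42) and Upp1 (5.76 ± 0.70), and Arg1 rose by 4.60 ± 0.33. Under the combination Ptges (7.88 ± 0.29), Ch25h (7.63 ± 0.38) and Oasl1 (7.59 ± 0.41) rose, and Atf3 (-5.99 ± 0.13) and the stress gene Sesn1 (-5.40 ± 0.19) fell. From 1 h to 4 h Il1b was at -4.11 ± 0.20 under PGE2, -1.85 ± 0.17 under TNF and 0.13 ± 0.16 under the combination, the last not past the threshold. Tnf changed by -1.17 ± 0.09, 1.14 ± 0.08 and 0.85 ± 0.08 in the same order, and Ptgs2 by -3.59 ± 0.12, -2.35 ± 0.13 and -2.18 ± 0.10. Il10 was at -2.52 ± 0.25, -1.67 ± 0.14 and -0.20 ± 0.12 and Cxcl2 at -2.39 ± 0.16, -0.79 ± 0.13 and 0.04 ± 0.13, with the combination not past the threshold for either. Il10 passed it there at -0.30 with scaling by total count only.

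Immediate early genes were lower at 4 h than at 1 h in each treatment, in 14, 13 and 13 of 16 members under PGE2, TNF and the combination (15, 13 and 13 adjusted over the list alone), with 1, 1 and 2 higher (1, 1 and 2). Cholesterol synthesis genes were higher in 18, 17 and 17 of 19 members (18, 17 and 17 adjusted over the list alone) and lower in 1, 1 and 1 (1, 1 and 1). Between the times 3491 genes rose and 3658 fell under PGE2, 4030 and 4206 under TNF and 4001 and 4295 under the combination. Under PGE2, TNF and the combination 48.8%, 48.9% and 48.2% of calls were higher at 4 h, against 52.7%, 30.7% and 41.5% with scaling by total count only, which moved the median gene by -0.287 under TNF and -0.106 under the combination.

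Markers of other cell types were summed per library. The neutrophil list, in which Csf3r, a receptor for the growth factor G-CSF, was the most abundant at 144 ± 2.38 CPM, summed to 215 ± 15.0 CPM in untreated cells. With PGE2, TNF and the combination the sums were 243 ± 2.04 CPM, 264 ± 19.3 CPM and 279.8 ± 9.99 CPM at 2 h and 103 ± 9.02 CPM, 178 ± 18.1 CPM and 130.0 ± 1.41 CPM at 4 h. In the B cell list Ighm, the immunoglobulin heavy chain gene, stood at 277 ± 4.74 CPM in untreated cells. The list summed to 287 ± 5.89 CPM in untreated cells and to 134 ± 5.26 CPM, 89.3 ± 7.71 CPM and 117 ± 3.18 CPM at 4 h of PGE2, TNF and the combination, and at 1 h to 267 ± 9.90 CPM, 252 ± 1.43 CPM and 292 ± 22.1 CPM. The dendritic cell list summed to 14.0 ± 0.508 CPM in untreated cells, 43.2 ± 4.38 CPM with the combination at 2 h and, at 4 h, 13.9 ± 0.415 CPM, 27.1 ± 3.91 CPM and 42.0 ± 3.69 CPM with PGE2, TNF and the combination. Of its 8 members tested, Ccr7, a lymph node homing receptor (3.51 ± 0.31), Xcr1 (5.16 ± 0.38) and Zbtb46 (3.21 ± 0.24) had risen with the combination at 2 h, Itgax had fallen (-0.71 ± 0.24) and 4 did not pass the threshold. Itgax did not pass it without TNF+PGE2 2 h replicate 3 (-0.65), without untreated replicate 3 (-0.61) or without the 3 libraries set aside (-0.61). Adjusted over the list alone, 4 were higher and 1 lower, and the list was not called (adjusted p over the marker lists = 0.063). The osteoclast list summed to 202 ± 13.0 CPM in untreated cells and in treated groups to between 142 ± 21.1 CPM (the combination at 2 h) and 216 ± 5.42 CPM (TNF at 1 h). Fibroblast markers, which would include any L929 cells, summed to at most 12.2 ± 18.0 CPM on average. T cell markers summed to at most 1.89 ± 0.709 CPM, mast cell markers to at most 1.47 ± 0.465 CPM and erythroid markers to at most 0.628 ± 0.243 CPM. Mitochondrial transcripts took between 0.721% and 1.271% of counts and the 50 most abundant genes between 31.3% and 35.06%. TNF 4 h replicate 1 and TNF+PGE2 4 h replicate 1 had the most genes detected (21875 and 22155), and TNF+PGE2 2 h replicate 3 lay farthest from its partners, with a chi-square per degree of freedom of 33.0 and 43.8. Among libraries of TNF at 4 h it was replicate 2 that lay farthest from its partners, at 28.9 and 23.2, against 10.0 between the other 2.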

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

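The interaction, the comparison of 4 h with 1 h and the other scalings were planned. The tests of explanations built on them, the fit without 3 libraries and the counts of other splits were chosen after the results were seen. Groups of 3 libraries are too small to test whether a library lies apart from its partners.

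The interaction passed its test in 169 genes at 1 h, 2708 at 2 h and 5106 at 4 h. Of these, 47, 1457 and 2675 had moved the same way in all 3 treatments. With 1 untreated group for all times, a change over time in culture shared by all treated cells would also enter the interaction, so the counts are not of differences in the PGE2 effect alone. At 4 h the interaction was 5.89 for Il1b, 5.21 for Il10, 2.21 for Ptgs2, 1.14 for Cxcl2 and -0.57 for Tnf on the log2 scale. Within a treatment, 7149 genes differed between 4 h and 1 h of PGE2, 8236 between 4 h and 1 h of TNF and 8296 between 4 h and 1 h of the combination.

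Immediate early genes stood above the sum of the single treatments at 4 h, with a median interaction of 1.78. Under other scalings the median was 1.858 (total count only) and 1.768 (RLE size factors), so scaling does not account for it. A fall over time in every culture, treated or not, may still have a part in it: 8 of 16 members were below untreated cells at 4 h in all 3 treatments, and without untreated cells of that time this cannot be told apart from the treatments. The list median was -0.026 between the combination and TNF alone at 4 h, with 6 of 16 members higher and 4 lower. It was -1.569 between PGE2 and untreated cells, the comparison that such a fall would enter. A different response to PGE2 in the presence of TNF stays among the open explanations.

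Interferon response genes were lower with the combination than with TNF alone at 4 h, with a median of -1.49. The median stayed at -1.390 with total count only and -1.493 with RLE size factors. Without the 3 libraries set aside, 20 of 24 members were lower, so neither scaling nor those libraries account for it. Without TNF 4 h replicate 2, which lay far from its partners, 24 of 24 were lower, so that library does not account for it either. Less Ifnb1 mRNA beforehand is a candidate explanation that stays open. The difference in Ifnb1 was -1.10 ± 0.56 (log2, SE) at 1 h (adjusted p = 0.297), and -0.414 there without TNF 1 h replicate 2. At 2 h it was -0.041 ± 0.462, and the values at both times are too wide to decide. At 4 h itself it was -1.26 ± 0.47 (adjusted p = 0.03), a call lost in 5 alternative fits and one that does not show what came before. The list's call itself did not hold with an estimated correlation (adjusted p = 0.29 with an estimated correlation).

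The summed B cell markers were lower after 4 h of each treatment. Cd79a, Cd19, Ms4a1, Pax5 and Igkc gave only 0.131% of the sum in untreated cells, and B cells would bring these too, so a loss of B cells does not account for the change. The rest of the sum came from Ighm and Cd79b, with 21746 and 770 counts over the untreated libraries. What lowered the sum was not tested.

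Other splits of the libraries were counted for each comparison, in fits of only the groups compared. Groups of 3 against 3 allow 10 splits, too few for a share under 0.05: in each of the 18 such comparisons the real split, which called from 1266 to 8217 genes, was 1 of the 10 and the highest of the others called 0. For the interaction 100 of 200 splits were counted, and 2 gave as many genes as the real one, itself included, at each time. Apart from the real split and one with exchanged labels, put in on purpose, they mixed libraries with and without PGE2 within an arm. Such mixing widens the spread, so these splits cannot decide whether chance gave the interaction. Real counts were 321, 2263 and 5152, against 1865, 4655 and 7090 for a split that exchanged the PGE2 labels in 1 arm and so measured the effect of PGE2 itself, and 241, 2218 and 3296 at most for the rest. For genes above both single treatments 100 of 840 splits were drawn: 1 at 1 h, 1 at 2 h and 3 at 4 h gave as many, the real one included. Real counts were 286, 372 and 898, with 182, 333 and 932 as the highest of the others. These splits mixed libraries of all 3 treatments, so they cannot decide whether chance gave these genes.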

How the results depend on the processing

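Of the alternatives, only the fit without the 3 libraries set aside was chosen after the data were seen. No value of a named gene past the threshold changed direction. With total count only, the side with more calls turned in several comparisons, for example from 42.7% to 54.3% higher for the combination against TNF at 4 h and from 37.3% to 53.3% above the sum for the interaction at 2 h, and medians of lists near 0 changed sign, for example from 0.06 to -0.18 for glycolysis and hypoxia with the combination at 4 h. Of 69 counts of genes, DESeq2 kept 66 within 1.5 times, no filter on low counts 66, only the groups compared 63, scaling by total count only 54 and the fit without the 3 libraries 66. RLE size factors kept all 70, the gene set count included, and leaving out 1 library at a time 465 of 486. The cause of the following changes was not tested. With total count only, the numbers were 1635 higher and 4243 lower for PGE2 at 2 h, 4794 lower for TNF at 2 h, 2609 higher for TNF at 4 h and 2628 higher for TNF at 4 h against 1 h. For the combination against untreated cells they were 1851 lower at 1 h and 1789 higher and 6103 lower at 2 h. Against TNF they were 808 lower at 1 h and 2587 at 2 h, against PGE2 1091, 2468 and 5624 lower at 1, 2 and 4 h, and below both single treatments 254 at 1 h and 862 at 2 h. With only the groups compared, 1013 were lower than TNF and 740 lower than PGE2 at 2 h, and 193 were below both. The interaction at 1 h gave 321 genes with only the groups compared (152 above, 169 below), 301 with no filter (158, 143), 302 with DESeq2 (143, 159) and 258 without the 3 libraries (149 below), where 126 were below both at 1 h. Leaving out 1 library gave from 232 to 290 genes lower with TNF at 1 h, 229 to 308 lower with the combination than with TNF at 1 h, 100 to 161 for the interaction at 1 h (36 to 79 above the sum), and 47 to 71 and 229 to 397 below both at 1 h and 2 h. Of 2616 values of named genes under the alternatives, 11 changed side of the threshold. Those that came past it were Cxcl10 in the interaction at 4 h with DESeq2 (-2.24) and with only the groups compared (-2.10) and Il10 in the combination at 4 h against 1 h with total count only (-0.30). Those that lost it were of Itgax with the combination at 2 h against untreated cells, without the 3 libraries (-0.61) and in 2 of the fits that left out 1 library (-0.65 and -0.61), and of Ifnb1 with the combination against TNF at 4 h, without the 3 libraries (-1.07) and in 4 of the fits that left out 1 library (-1.09, -1.29, -1.25 and -1.10). Of 420 pairs of a list and a comparison, 236 were called, 122 with an estimated correlation, 318 with fry and 237 with RLE size factors. Replicate numbers did not pair the libraries throughout: 55 of 135 same-number correlations were above 0.1 (mean 0.030), 13 of 30 libraries correlated best with their own number, and every correlation was above 0.1 in 5 of 45 pairs of groups. Of these, 2 are comparisons made here, the combination against PGE2 at 1 h and TNF at 4 h against 1 h. The replicate block changed no call of a named gene and moved no count by over 1.5 times, and with it 240 pairs of a list and a comparison were called. Depth, from 15062499 to 35175270 counts per library, limits genes near the floor of 3 counts over a group.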

Other observations

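The test in this part of a gene's change used the contrasts fixed before the data were examined, but the genes described were chosen by their size of change or as list members not described above. Among receptors for PGE2, Ptger2 was higher with the combination than with TNF alone at 4 h (1.62 ± 0.22), whereas Ptger4 was lower, as given above. Ptger3 had 0 counts over the group with the combination at 4 h, against 9 with TNF, 26 with PGE2 and 39 in untreated cells. Abcc4, a transporter that can export prostaglandins, was higher with the combination than with TNF at 4 h (1.84 ± 0.10). Nt5e, which makes adenosine from AMP, rose with PGE2 at 4 h (5.92 ± 0.25) and was higher with the combination than with TNF at 1 h (3.39 ± 0.34). Thbd, the anticoagulant receptor thrombomodulin, was higher with the combination than with TNF at 2 h (5.25 ± 0.11), and Procr, the receptor of protein C, stood above the sum of the single treatments at 1 h (1.97 ± 0.36). Slc7a11, the cystine transporter gene, rose to 6.13 ± 0.18 with the combination at 4 h, and Me1 and Txnrd1, which supply reducing power, to 3.10 ± 0.80 and 2.46 ± 0.14.

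Not every member of a list moved with it. Rgs2, a regulator of G protein signalling in the cyclic AMP-CREB list, was lower with the combination than with TNF at 4 h (-3.17 ± 0.11) while Crem and Nr4a2 were higher (3.72 ± 0.10 and 3.82 ± 0.20). Tlr5 and Tlr9, receptors for flagellin and CpG DNA, fell with TNF at 4 h (-2.69 ± 0.26 and -1.76 ± 0.18) while Tlr2, a receptor for lipoproteins, rose (3.48 ± 0.09). Among CC chemokines, Ccl9 rose with PGE2 at 4 h (1.15 ± 0.10) while Ccl3 and Ccl4 fell.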
